A study of Homo sapiens with 6 samples.

How the data were processed

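RNA was measured in 6 libraries of the human lung adenocarcinoma line PC9, which carries an EGFR exon 19 deletion. The parental line and a gefitinib-resistant derivative, PC9-GR, gave 3 libraries each. Per the labels, each library came from an independent culture, total RNA was extracted with Trizol, and libraries were made with a strand-specific Agilent SureSelect kit. Gefitinib inhibits the EGFR kinase. PC9-GR was selected with rising doses from 0.5 to 10 µM, was kept at 10 µM, and grew without the drug for 7 days before extraction.

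Per the submitters' processing notes, TopHat and Cufflinks were used. Their versions, the genome build, the annotation and the strand setting are not given in the sources used here. The deposited table holds FPKM per library and an FPKM per group, per the file headers. It also holds, per the file headers, the authors' ratio of PC9-GR to PC9, its log2 value, a p-value and a q-value. The ratio equals the quotient of the deposited group FPKM values to within a relative 3.2e-06. The lowest deposited FPKM is 0.001 in a library and 0.0001 in a group, and such entries were read as the floor of the table.

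The table is a selection and not a transcriptome. All 1705 genes in it have an authors' log2 ratio beyond 1 in either direction (smallest absolute value 1.0002) and an authors' p-value no larger than 0.04965. The authors' q-value reached 0.124, and it was under 0.05 for 1507 genes. Because the same 6 libraries chose the genes, every test reported here is conditioned on that choice and is not independent evidence that a gene differs. The share of tested genes that pass a threshold says nothing about the share in the transcriptome. Genes outside the table were not analysed here.

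FPKM was used as deposited on the scale log2(FPKM + 1), so a log2 difference given below understates the change of low genes. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, which kept 1207 genes and left out 498. The test was the two-sided moderated test of limma 3.58.1 in R 4.3.3, with a variance trend, group as the only term and Benjamini-Hochberg adjustment, called at adjusted p under 0.05. Folds given in the text are ratios of mean FPKM. AATK fell below the filter and was tested with a two-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. On simulated data with the spread of the 1207 tested genes, the limma step recovered 66% of genes changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 4-fold. In that simulation it called 13 of 1007 unchanged genes. The table itself holds only genes chosen as changed, and the simulated spread comes from these chosen genes. The simulated rates therefore check the step and do not describe its error on this table.

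Before the data were examined, 31 gene lists were fixed. A list with at least 5 tested entries was tested with camera in limma at a preset inter-gene correlation of 0.01, which applied to 10 lists. Camera compares a list with the other genes of the table, all of which were selected as changed. Counts adjusted over the list alone were equal to those over all genes tested in each of the 31 lists. After the data were seen, a Fisher's exact test was added that compares the direction of the authors' ratio between a list's entries and the other genes of the table.

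Named genes followed a rule fixed before the data were examined. It took AATK, TFRC, RAB11A, CDK5, GPX4, SLC7A11, ACSL4, FTH1, EGFR and MET, of which only AATK is in the table. It took the 10 largest increases and the 10 largest decreases among called genes whose groups did not overlap and whose higher group averaged at least 5 FPKM, leaving out clone names, repeated symbols, XIST and Y-linked genes. It also took up to 2 called members per direction in each list. Genes outside the rule are also named where they spell out a count of 5 or fewer, are the exception in a list, lose or gain a call, or bound a run of genes, and any others are marked where they appear.

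The position of genes was taken from the loci of the deposited table. The table names no build. Of 1655 gene identifiers found in GENCODE 29, which is on GRCh38, 54 have a GRCh38 position inside the table's locus, so coordinates of the 2 sources were not mixed. Loci are those of the table and can cover more than the gene: that of AATK spans 148018 bp, against 48783 bp for the gene in GENCODE 29. A locus shared with another listed gene was found for 205 genes, and their values are uncertain where reads could be split between them. Positional tests used shuffled directions (100000 permutations), and GC content came from GENCODE 29 transcripts matched by identifier. Positional steps used Python 3.11.15 with scipy 1.17.1, and odds ratios within GC strata are Mantel-Haenszel estimates from statsmodels 0.14.6.

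The table has no counts, so sequencing depth per library is unknown and no counting interval is given. The number of listed genes at 1 FPKM or more ranged from 987 to 1002 in PC9 and from 1116 to 1150 in PC9-GR. Replicates within a group correlated at a Pearson r across genes of 0.9766 to 0.986, where genes are not independent replicates, and no pair of libraries was identical. Alternatives covered the pseudocount, the filter, the scaling, the variance model, leaving out each replicate, a replicate block, a stricter threshold, an inter-gene correlation estimated from the data, and fry. Fry asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. Count-based tests planned for a count table were not run, as the values are FPKM.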

Results

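Expression was compared between parental PC9 cells and gefitinib-resistant PC9-GR cells, with 3 libraries from independent cultures in each group. The series concerns lowered AATK, recycling of endosomes and susceptibility to ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation, in the resistant cells. The deposited table lists 1705 genes that the authors had already selected as changed, 871 with a higher and 834 with a lower ratio in PC9-GR. Sequencing depth is unknown, since the table holds FPKM without counts. All values are mean FPKM ± SD with n = 3 libraries per group unless stated otherwise.

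AATK, a kinase that the series title names as lowered in the resistant cells, was low in both lines and lower in PC9-GR. It measured 0.468 ± 0.0785 FPKM in PC9 and 0.0779 ± 0.0363 FPKM in PC9-GR, a 6.01-fold difference. The lowest PC9 library (0.4164 FPKM) lay above the highest PC9-GR library (0.1194 FPKM). AATK (ENSG00000181409) is placed on chromosome 17 at 79008947 to 79156964 in the table, whose build is not named. The two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow, so significance at 0.05 was out of reach. The authors' deposited table gives AATK a log2 ratio of -2.61 and a q-value of 0.0191. Without the filter on low values, limma gave AATK an adjusted p of 0.000526, and over the other alternatives p ran from 0.1 to 0.25.

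Genes with higher levels in resistant cells included COL6A3, VIM, SPARC and SCD, and genes with lower levels included MAGEA4, KRT13 and SPRR1B. Of 1207 genes tested, limma called 584 higher and 619 lower in PC9-GR, and 4 were not called. A difference of at least 2-fold on the log2(FPKM + 1) scale was found for 366 higher and 419 lower genes. The counts were 556 and 592 with a pseudocount of 0.1, and 196 and 335 with a filter at 5 FPKM. With equal library totals these counts were 566 and 110, and with median-ratio scaling 232 and 535, so which side is larger depended on the scaling. The totals are sums over the listed genes alone, 28346 to 30541 FPKM in PC9 and 16705 to 17114 FPKM in PC9-GR, and HSP90AA1, itself called lower, makes up 16.9% to 17.5% and 5.6% to 7.7% of them. The groups did not overlap for 1617 of the 1705 listed genes (94.8%), against 10% by chance, but the list had been chosen on these libraries. Of the calls, 48.5% were higher as deposited and 57.5% with equal library totals. With equal totals, higher calls hardly changed (586), lower calls were fewer (433), and the median gene moved by 0.61 on the log2 scale. With a filter at 5 FPKM, 37.3% were higher.

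COL6A3, a collagen VI chain, rose from 0.317 ± 0.0844 to 28.2 ± 0.942 FPKM, and the matrix metalloprotease MMP9 rose from 0.261 ± 0.135 to 13.8 ± 0.873 FPKM. Vimentin (VIM), a mesenchymal intermediate filament, rose 12.3-fold from 21.9 ± 1.12 to 270.1 ± 19.6 FPKM, and SPARC, a matrix glycoprotein, rose 11.7-fold to 231.7 ± 16.7 FPKM. The cytokine IL32 rose 27.6-fold, the guidance factor SEMA3E 25.9-fold and the cadherin CDH13 50.3-fold. The size of the CDH13 fold is uncertain, as PC9 measured only 0.204 ± 0.158 FPKM. The non-coding RNA H19 rose 15.8-fold, and CTGF, a secreted matrix-associated protein, rose 11.7-fold. SCD, which desaturates fatty acids, rose 20.2-fold from 1.10 ± 0.389 to 22.3 ± 5.72 FPKM. Each of these 10 genes passed limma at adjusted p under 0.05 in each alternative run. They had been picked as the largest increases among called genes, so this adds little.

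MAGEA4, a cancer-testis antigen, measured 20.6 ± 0.672 FPKM in PC9 and was listed at the floor in the 3 PC9-GR libraries, so no fold is given. KRT13 fell 58.3-fold from 31.2 ± 2.99 to 0.534 ± 0.234 FPKM. The cornified envelope precursors SPRR1B, SPRR3 and SPRR1A fell 20.9-fold, 35.2-fold and 12.0-fold, with SPRR1B the most variable at 247.1 ± 107.5 FPKM in PC9. The microfibril protein MFAP5 fell 14.5-fold, the adhesion receptor GPR116 15.8-fold, the chemokine scavenger ACKR2 39.9-fold and the phosphodiesterase PDE2A 14.6-fold. The size of the ACKR2 fold is uncertain, as PC9-GR measured only 0.274 ± 0.209 FPKM. MOCOS, which matures the molybdenum cofactor of xanthine dehydrogenase and aldehyde oxidase, fell 12.0-fold and lies in a stretch of chromosome 18 where neighbouring genes were also lower.

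**Figure D1:**
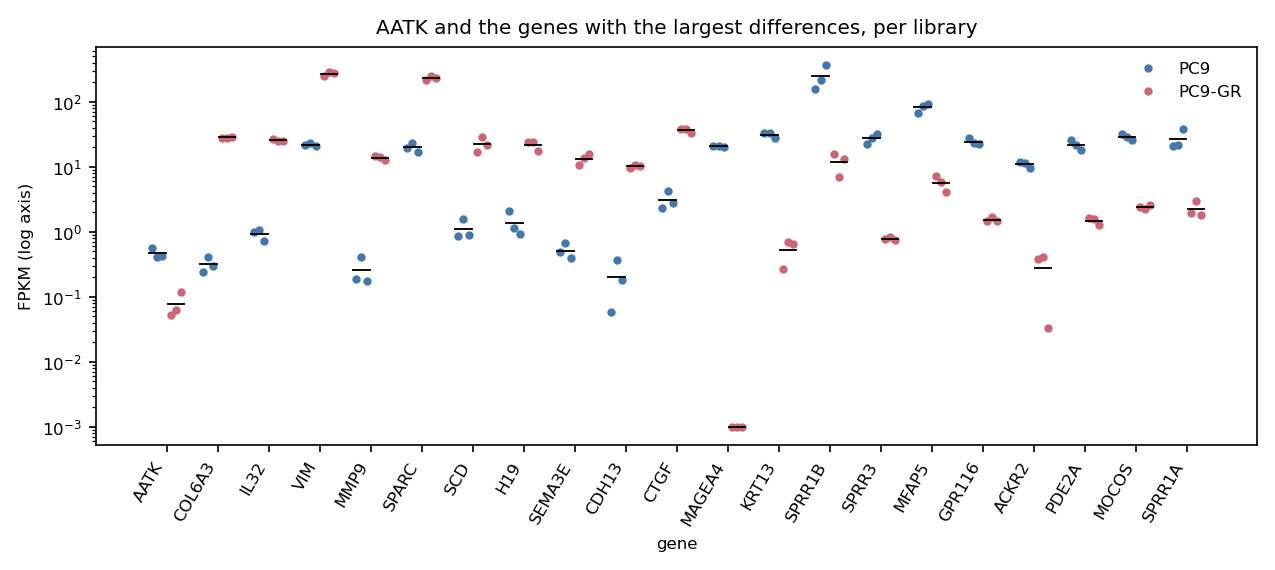
FPKM on a log axis of AATK, the 10 largest increases and the 10 largest decreases, with PC9 libraries in blue, PC9-GR libraries in red and a bar at each group mean (3 libraries per group). No gene shown has overlapping groups, and MAGEA4 sits at the floor of 0.001 FPKM in PC9-GR.

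Mesenchymal markers in the table were higher in PC9-GR. Of 32 list members, 14 are in the table. All 14 were called higher, including VIM and SPARC, and 0 were called lower. VIM lies in a run of consecutive higher genes on chromosome 10. How many other members lie in runs of higher genes was not counted, so VIM need not be the only one. Outside the naming rule, and chosen after their values were seen, the transcription factors ZEB1 and ZEB2 rose 6.06-fold and 12.7-fold and N-cadherin (CDH2) rose 10.6-fold. Camera gave the list an adjusted p of 0.000217, and the adjusted p was 0.197 with an estimated correlation. Of 30 epithelial markers only CLDN1, a tight junction protein, and OVOL1, an epithelial transcription factor, are in the table. CLDN1 fell from 86.8 ± 11.0 to 26.0 ± 5.02 FPKM and OVOL1 fell 3.44-fold. Among markers of other cell types, PDGFRB was the only endothelial or fibroblast marker listed and rose from 0.0948 ± 0.0423 to 3.28 ± 0.780 FPKM. The haematopoietic markers CORO1A, CD68, ITGAX and ITGAM were called higher, with ITGAX at 2.83 ± 0.187 and CD68 at 38.4 ± 3.61 FPKM in PC9-GR. The remaining member, LYZ, was below the filter at 1.09 ± 0.459 FPKM in PC9 and 0.142 ± 0.125 FPKM in PC9-GR, and it was called lower without the filter.

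Squamous lineage genes in the table were mostly lower, and so were the few lung lineage genes listed. Of 21 squamous markers, 11 are in the table, and 10 of these were called lower and 0 higher. TRIM29 lost its call with equal library totals (limma adjusted p = 0.0922) and under quantile normalization (limma adjusted p = 0.064). The remaining member in the table, the desmosomal cadherin DSG3, was below the filter at 0.402 ± 0.0296 FPKM in PC9 and 1.01 ± 0.208 FPKM in PC9-GR. Without the filter it was called higher. SPRR3 fell 35.2-fold, and the keratin KRT6B fell 4.63-fold from 87.3 ± 14.02 to 18.9 ± 1.20 FPKM. The squamous list had a camera adjusted p of 0.00348, and the adjusted p was 0.379 with an estimated correlation. Of 23 lung lineage markers only 3 are in the table, with 4 entries, all called lower: FOXA1, LPCAT1 and CEACAM6, the last under 2 identifiers. CEACAM6 fell 82.6-fold at its chromosome 19 entry and 61.0-fold at a patch scaffold entry, and these values are uncertain because reads can be shared between the copies. The chromosome 19 entry was also low and variable in PC9-GR, at 0.101 ± 0.0888 FPKM. RIMS2 was the only tested neuroendocrine marker and rose 4.69-fold. Of the cancer-testis antigens tested, CTAG2 rose 2.55-fold and MAGEA4 fell.

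Sterol and fatty acid genes in the table were mostly higher. Of 24 cholesterol synthesis genes, 8 are in the table. All 8 were called higher, among them STARD4, a sterol carrier, and INSIG1, a sterol-regulated brake on SREBP processing. Members IDI1 and LSS bound runs of consecutive higher genes on chromosomes 10 and 21. STARD4 rose from 0.0925 ± 0.0837 to 3.23 ± 0.384 FPKM, and INSIG1 rose 4.78-fold to 7.93 ± 0.576 FPKM. Camera gave an adjusted p of 0.00852, and the adjusted p was 0.253 with an estimated correlation. In the fatty acid list, SCD and the desaturase FADS2 rose, the latter from 9.83 ± 1.04 to 20.9 ± 2.88 FPKM. ACSL5, an acyl-CoA synthetase, fell 2.90-fold.

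Few genes of the lists closest to the series' subject were in the table. Of 30 recycling endosome genes, AATK and MYO5B are listed. MYO5B, a motor of recycling endosomes, fell 6.71-fold from 107.2 ± 3.68 to 15.96 ± 4.44 FPKM, and it too lies in the chromosome 18 stretch. The list fixed for ferroptosis-promoting lipid enzymes also holds members that are not lipid enzymes, such as CHAC1 and NOX1. From it, ALOX15, FADS2 and CHAC1 were called higher, but CHAC1 lost its call under quantile normalization (limma adjusted p = 0.0785). The lipoxygenase ALOX15 rose 4.95-fold to 2.15 ± 0.158 FPKM. NOX1 and ALOXE3 were below the filter, and without it NOX1 was called lower (limma adjusted p = 0.0187) and ALOXE3 higher (limma adjusted p = 0.0342). Of the ferroptosis defence list, SCD and SQLE were called higher, with SQLE, an enzyme of sterol synthesis, at 21.3 ± 3.06 and 53.0 ± 3.12 FPKM. HMOX1, which degrades haem and belongs to both the iron and the NRF2 lists, rose 2.26-fold, and the NRF2 target OSGIN1 rose 1.98-fold.

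Receptors and ligands moved in both directions. PDGFRB and FGFR1 were called higher, and ERBB2 and MST1R lower. FGFR1 measured 14.1 ± 1.15 in PC9 and 37.95 ± 4.48 FPKM in PC9-GR, and ERBB2 measured 45.7 ± 1.67 and 21.4 ± 2.49 FPKM. MST1R lost its call with equal library totals (limma adjusted p = 0.276, against 0.000137 to 0.00386 in the other alternatives). Of 8 ligands, 4 were called higher and 4 lower, and with equal library totals 4 were higher and only 1 lower. The list had a camera adjusted p of 0.586, and its median log2 difference was 0.17 as deposited and -0.04 under quantile normalization. FGF2 rose 27.0-fold to 6.02 ± 0.575 FPKM and NRG1, a ligand of ERBB3 and ERBB4, rose 7.13-fold to 14.4 ± 3.30 FPKM. The EGFR ligand HBEGF fell 3.06-fold from 44.0 ± 2.84 FPKM. TGFA fell 2.36-fold, and it was among the 3 ligands that lost their call with equal library totals (limma adjusted p = 0.0694, against 4.86e-05 to 0.00142 in the others).

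Of 20 transcripts that report on MAPK signalling, 7 are in the table. All 7 were called lower, and 4 of them were still called with equal library totals. The Sprouty gene SPRY2 fell 2.43-fold from 14.1 ± 0.431 FPKM and the ephrin receptor EPHA4 fell 4.31-fold from 9.28 ± 0.181 FPKM. The camera adjusted p was 0.0346, and the adjusted p was 0.253 with an estimated correlation and 0.104 with a filter at 5 FPKM. Of 22 YAP and TAZ targets, 5 are in the table. All 5 were called higher, with ANKRD1 rising 4.99-fold beside CTGF. This list had a camera adjusted p of 0.0238, and the adjusted p was 0.293 with an estimated correlation.

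Smaller groups followed. Of 24 amino acid response genes, 7 are in the table. The 5 tested genes were called higher, with ASNS rising 3.74-fold and STC2 2.55-fold, and CHAC1 is the member that lost its call under quantile normalization. Their camera adjusted p was 0.0472, and the adjusted p was 0.253 with an estimated correlation. The call was also lost without genes in positional runs (adjusted p = 0.0844), without PC9-GR replicate 2 (adjusted p = 0.0509) and with median-ratio scaling (adjusted p = 0.0504), and the camera adjusted p ranged from 0.0319 to 0.253 over its alternatives. Of 29 glycolysis and hypoxia genes, 5 are in the table. All 5 were called higher, with CA12 rising 3.90-fold and BNIP3 2.14-fold (camera adjusted p = 0.0392, adjusted p = 0.379 with an estimated correlation and 0.0727 without genes in positional runs). Of 23 antigen presentation genes, 3 are in the table. The 5 tested entries were called higher, but most are copies of HLA genes on alternative scaffolds and are uncertain, as the reads of such copies overlap. Their camera adjusted p was 0.0374, and the adjusted p was 0.309 with an estimated correlation and 0.0689 without genes in positional runs. No entry of the amino acid, glycolysis or antigen presentation list lies in those runs, which hold only lower genes. Leaving the runs out changed the genes that these lists are compared with. CD74 rose from 0.0770 ± 0.0478 to 1.24 ± 0.161 FPKM. Of 32 interferon response genes only IFI44, IFI44L, IFI6 and MX1 are in the table, and they were called higher, with IFI44 rising 6.82-fold. Of 7 cytokines tested, 4 were called higher and 3 lower (camera adjusted p = 0.47), and IL1B lost its lower call with equal library totals (limma adjusted p = 0.133). CCL2 was at the floor in PC9 and at 3.90 ± 0.737 FPKM in PC9-GR, whereas IL18 fell 3.09-fold and CSF2 3.79-fold. In the drug metabolism list GSTM3 rose 2.44-fold and ALDH3A1 fell 7.77-fold. BCL2, an apoptosis inhibitor and the only apoptosis regulator in the table, fell 2.70-fold from 1.99 ± 0.263 to 0.737 ± 0.125 FPKM. It lies on chromosome 18 between runs of lower genes, where most listed genes were lower. The heat shock and immediate early genes HSP90AA1, FOS and NR4A1 were called lower, and NR4A1 lost its call with equal library totals (limma adjusted p = 0.539). HSP90AA1 went from 5084 ± 226.4 to 1145 ± 168.9 FPKM, a call lost under quantile normalization, where as the top gene it is set equal in each library. FOS was variable in PC9 (19.5 ± 14.8 FPKM), and HSP90AA1 and FOS lie in stretches of chromosome 14 where neighbours were also lower. The lists fixed for proliferation, the unfolded protein response, ribosomal proteins and mitochondrial transcripts had 0 members in the table, although RPL17, a ribosomal protein gene outside the list and the naming rule, is there (authors' log2 ratio -1.411).

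The direction of the authors' ratio, compared between each called list and the other genes of the table by Fisher's exact test, gave an adjusted p of 0.00157 for mesenchymal markers. It was 0.0253 for the squamous, cholesterol synthesis and MAPK lists and 0.0406 for the amino acid response list. It missed 0.05 for antigen presentation (adjusted p = 0.0676), for glycolysis and hypoxia (adjusted p = 0.101) and for the YAP and TAZ targets (adjusted p = 0.101). The Fisher test counts genes as independent. Where genes of a list move together, its p-values are too small.

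**Figure D2:**
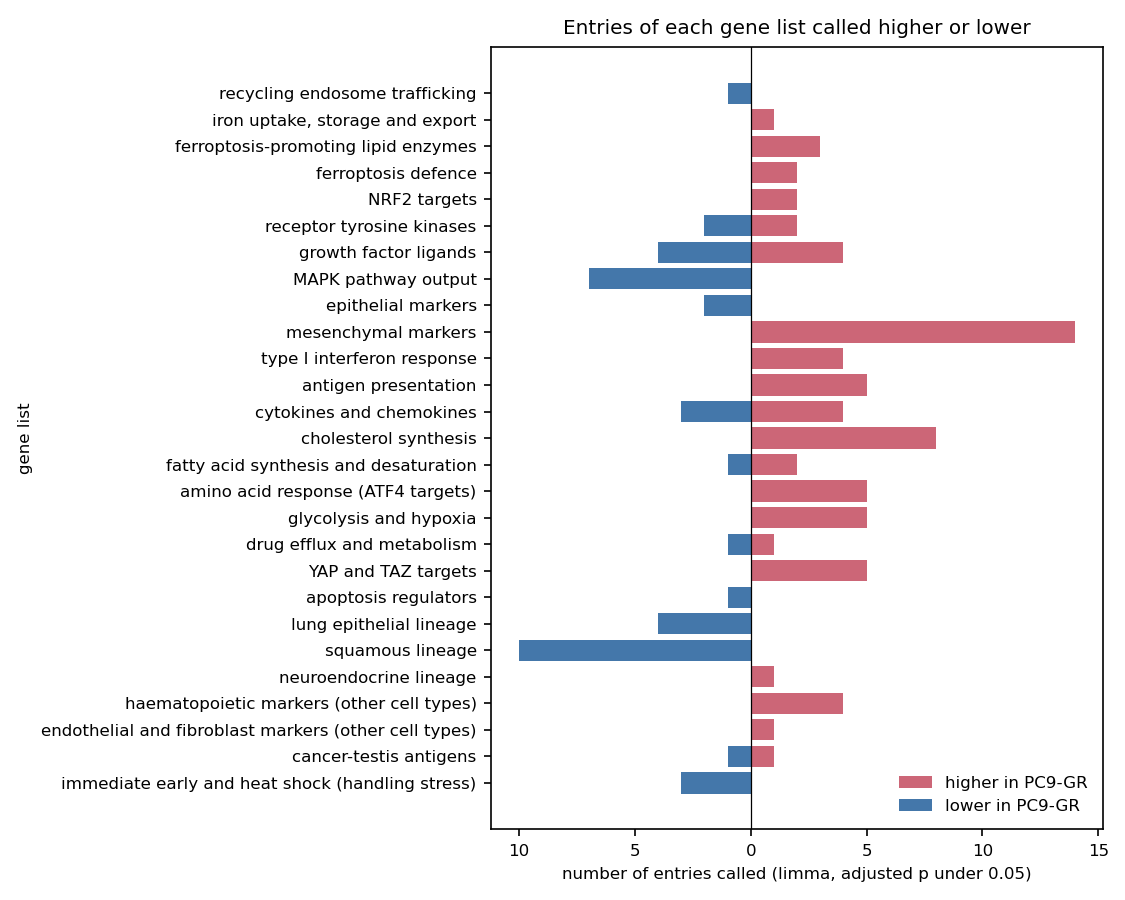
Number of entries of each gene list called higher (red, to the right) or lower (blue, to the left) in PC9-GR by limma at adjusted p under 0.05, for the 27 lists with a called entry. Mesenchymal markers reach 14 on the higher side and squamous markers 10 on the lower side.

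Lower genes were unevenly placed along the genome, a comparison made after the data were seen. On chromosome 18, 98 of 108 listed genes had a lower authors' ratio (90.7%; Fisher's exact test, adjusted p = 5.08e-20 over the chromosomes), and on chromosome 14 it was 74 of 93 (79.6%; adjusted p = 8.13e-09). Chromosome 3 also leaned lower, with 57 of 88 genes (adjusted p = 0.0112). The other way leaned chromosome 10 with 41 of 51 genes higher (adjusted p = 0.000106), chromosome 21 with 16 of 17 and chromosome 1 with 108 of 168 (adjusted p = 0.00152 for each). Weaker leans to higher genes were found on chromosome 4, with 52 of 78 (adjusted p = 0.0172), and on chromosome 15, with 31 of 45 (adjusted p = 0.0455). On chromosome 14, 41 consecutive listed genes from SMOC1 to ADCK1 (70320847 to 78401355) were lower, with a median authors' log2 ratio of -1.77. Another 27 were lower between 102100790 and 105965912, which include HSP90AA1. On chromosome 18, runs of 21, 38 and 25 lower genes covered most of the stretch from 29598334 to 78005429, with MYO5B and MOCOS among them. The 131 tested genes of the runs had a median log2 difference of -1.43 as deposited and -0.69 with equal library totals, where 116 were called lower. Shuffled directions exceeded a run of 13 lower genes in under 5% of permutations. Higher genes also formed a run of 20 on chromosome 10, from IDI1 to TACR2 (permutation p = 8e-04), which includes VIM. On chromosome 21 a run of 16 higher genes went from NCAM2 to LSS (permutation p = 1e-02).

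**Figure D3:**
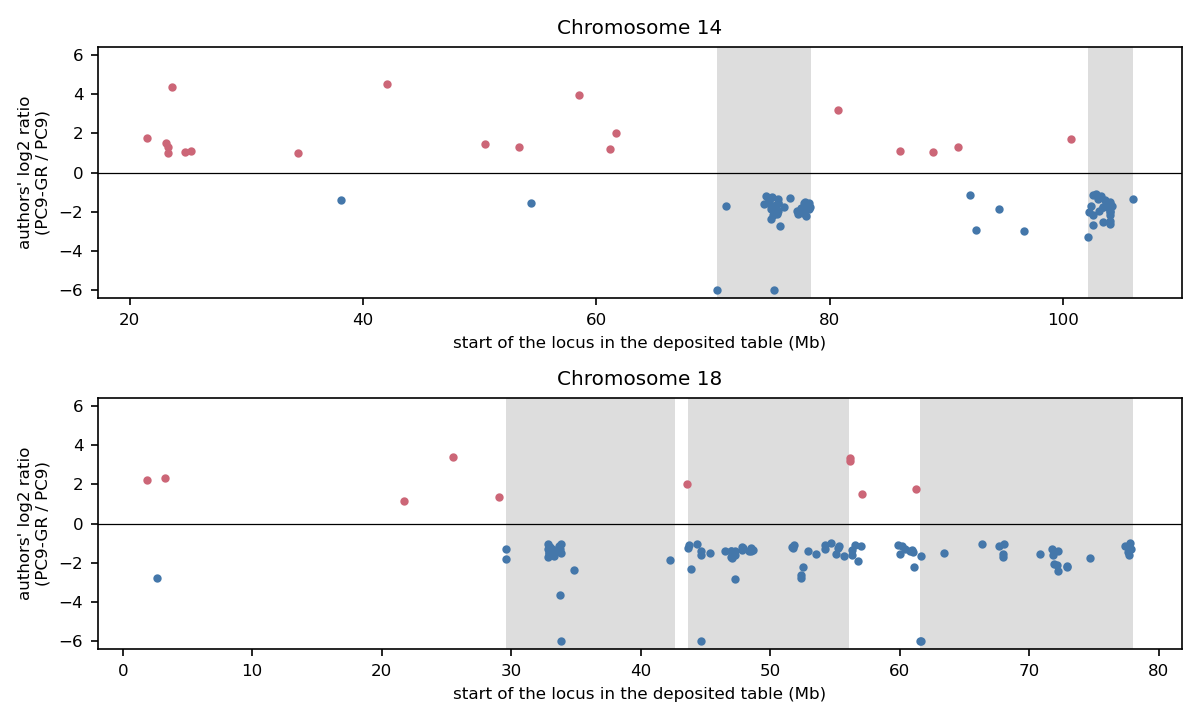
Authors' log2 ratio of PC9-GR to PC9 for each listed gene of chromosomes 14 and 18 against the start of its locus in Mb as the deposited table gives it, with higher genes in red, lower genes in blue and the 5 runs of lower genes shaded. The 6 genes beyond a log2 ratio of 6 in size are drawn at that limit.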

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

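All listed genes lie beyond 2-fold by the authors' ratio and the scalings shift the median gene by less, so a kept direction is not evidence of stability, and the calls and sizes are compared here. HSP90AA1 went from -2.159 to 0 under quantile normalization, and the median of the growth factor ligands, a list without a call, went from 0.17 to -0.04 there. The balance of calls did turn: lower genes outnumbered higher ones as deposited. The reverse held with equal library totals (586 higher, 433 lower) and without the filter (846 higher, 810 lower). Without the genes of positional runs, 585 were higher and 488 lower. This alternative was chosen after seeing the data and took out runs of lower genes only. All 131 tested genes of these runs had been called lower, so the turn there was fixed by their removal. Leaving out each replicate in turn gave 578 to 581 higher and 614 to 618 lower genes, 353 to 376 and 403 to 430 of them at least 2-fold, an AATK difference of -0.473 to -0.401 on the log2 scale and 7 to 8 called lists. A filter at 5 FPKM tested 629 genes and gave 234 higher and 393 lower genes, 196 at least 2-fold higher and 3 called lists of the 5 that still had enough entries to test. Genes at least 2-fold higher numbered 556 with a pseudocount of 0.1, 573 with 0.01, 566 with equal library totals and 232 with median-ratio scaling, while genes at least 2-fold lower numbered 592, 606, 110 and 535. The median gene was shifted by -0.01, -0.011, 0.61 and -0.232 in these 4 alternatives. Without the filter, AATK kept its difference of -0.445 with an adjusted p of 0.000526 from limma, which there takes the place of the exact permutation test. List calls fell from 8 to 0 with an estimated correlation and to 5 without positional runs, where antigen presentation (0.0689), glycolysis and hypoxia (0.0727) and amino acid response (0.0844) were lost. No entry of these lost lists lies in the runs, so what changed was the genes they are compared with. Over the alternatives, named genes kept their call in 1025 values and lost it in 3. This says little about stability, since 99.7% of tested genes were called as deposited and the named genes were picked from these. Among all 1207 tested genes, 188 were not called with equal library totals. List tests kept their side of the threshold in 169 values and lost it in 14, while 2 gained it, both with fry, which called 10 lists. Counts of called list members stayed within 1.5 times in 842 values, fell further in 14 and rose further in 8. Deviations of libraries with the same replicate number correlated at -0.098, 0.082 and 0.164, and not every library correlated best with its own number. So few correlations, over genes chosen on these libraries, cannot decide whether replicate numbers pair the samples. With the replicate block 586 genes were higher and 619 lower, 366 and 419 of them at least 2-fold, 8 lists were called, and AATK kept -0.445 with an exact p of 0.25 (smallest possible for 3 pairs). Depth is unknown, so low genes such as AATK cannot be given a counting error.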

Other observations

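All tests of explanations in this part were chosen after the result was seen. Collagen genes and zinc finger genes moved apart. Of 14 listed genes whose symbols begin with COL, 12 had a higher authors' ratio (Fisher's exact test, adjusted p = 0.045 over 7 symbol families). How many of them lie in the runs of higher genes was not counted. COL4A1 rose from 0.205 ± 0.0774 to 3.95 ± 0.736 FPKM and COL5A1 rose 9.69-fold (n = 3 per group), while COL17A1, a hemidesmosome collagen, fell 4.81-fold and COL8A1 fell 4.18-fold. These genes were picked after their values were seen.

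Genes with ZNF symbols, mostly zinc finger proteins, leaned lower, with a lower authors' ratio in 30 of 36 (adjusted p = 0.000185 over the same 7 families), and of the 26 tested, 21 were called lower as deposited and 13 with equal library totals (median log2 difference -0.92 and -0.32). All 6 on chromosome 18 and all 17 on chromosome 19 were lower, and the other 13 split into 7 lower and 6 higher. Placement on chromosomes 14 and 18 alone is argued against, since without them the odds ratio for lower direction was 5.25, and so is GC content, since within GC quintiles it was 4.93 (95% interval 2.02 to 12). Placement on chromosomes 18 and 19 stays open, since without them the odds ratio was 1.41 (Fisher p = 0.585) over few genes, although on chromosome 19 only 47 of the 100 other listed genes were lower (Fisher p = 1.97e-05 against its ZNF genes). The chromosome 19 entries include ZNF816, ZNF816-ZNF321P and ZNF702P at the same locus and ZNF582-AS1 beside ZNF582, all named outside the rule. The tests count such entries as separate genes, so their p-values and interval are too narrow to that extent. Reads shared between neighbouring ZNF genes were not tested, and neither was a biological explanation.

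The runs of lower genes on chromosomes 14 and 18 hold 152 genes. GC bias is argued against: the odds ratio for lower direction on these chromosomes was 7.77 overall and 7.59 within GC deciles (95% interval 5 to 11.5). Reads shared between overlapping genes are argued against, since with 1 gene kept per set of overlapping loci the longest run was still 32 genes, against 12 at the 95% point of shuffled directions. A candidate explanation is a difference in chromosome copies, and the ratio cannot tell a loss in PC9-GR from a gain in PC9. Of the coding genes annotated in these spans, 47.6% are listed as lower, against 2.6% elsewhere. The spans were drawn from runs of lower genes in the same data, so part of this contrast was fixed in advance. The spans of the runs of higher genes on chromosomes 10 and 21, drawn likewise, have 5.2% and 4.6% listed as higher. No DNA was measured, so broad silencing also stays open. The median ratio may exaggerate a copy change, because the table keeps only genes beyond 2-fold, but by how much is unknown. For genes above the floor, the quartiles of the authors' log2 ratio were -2.0 and -1.57 in the 41-gene run on chromosome 14. In the 38-gene run on chromosome 18 they were -1.62 and -1.25.

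The 6 libraries can be split in only 10 ways, too few for a share under 0.05. The real split called 1203 genes and the highest other split 0, and for genes at least 2-fold apart the real split gave 785 and the highest other 0. The listed genes had been chosen as different in the real split, so this contrast was largely fixed in advance and is not evidence. For gene lists the real split called 8 and the other splits 2 to 7. In each of these 3 results, 1 of the 10 splits was as large, the real one. Each other split still sets libraries of both lines unevenly against each other, so part of the real difference remains in it.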
